A study of Rattus norvegicus with 6 samples.

How the data were processed

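Total RNA was taken from medial prefrontal cortex of 6 rats, 3 Control and 3 CMS, and miRNA libraries were sequenced on an Illumina NextSeq, per the labels' protocols. The submitters' processing notes name the aligner Novoalign 2.07.11. Adapter trimming, the genome build, the miRNA annotation, the prediction of unannotated miRNAs and the scale of normalization are not given in the sources used here. The deposited table has 1 value per miRNA and library for 1465 miRNAs, 771 of them predicted. The authors' values are treated as a score, meaning a normalized expression value rounded to whole numbers. They are whole numbers, but they do not behave as raw reads. Library sums differ by only 3.72%, and for miRNAs with a mean of 1 to 8 the variance over replicates was 0.491 times the mean in Control (175 miRNAs) and 0.54 times in CMS (191 miRNAs), where counted reads cannot fall below 1 on average. Raw read numbers and depth are therefore unknown, and no interval or detection floor based on reads was computed. Rounding limits the precision of low values, since a value of 1 stands for a range of levels. Blank cells, which held between 778 and 840 of the rows per library, were taken as 0. For 711 miRNAs, 192 of them annotated, all 6 cells were blank.

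Samples were grouped by their titles. Tests were fixed before the data were examined. For normalized values the plan was limma-trend (limma 3.58.1 in R 4.3.3) on log2(value + 1), without further scaling, for miRNAs with a value of at least 1 in at least 3 samples, with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 change on this scale understates changes of low miRNAs. Folds are ratios of group means and are left out where a group is listed at 0. Exact permutation of 3 against 3 cannot give a two-sided p below 0.1, so single p-values come from the limma model, which shares the spread across miRNAs. The miRNAs named in the text are the up to 15 higher and up to 15 lower ones with the smallest p past the adjusted threshold, the 10 with the highest mean, and up to 4 members of each list with the smallest p. The first part leaves out 7 of the 27 calls, all higher in CMS. Any miRNA named outside the rule is said to be chosen after its values were seen.

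The 23 lists (neuronal, activity-linked, oligodendrocyte, astrocyte, microglial and immune, vascular, blood, choroid plexus with ependyma and epithelium, muscle, stress and mood, glucocorticoid receptor, hypoxia, the imprinted region, and 10 families and clusters) were written before the data were examined. An entry without an arm takes both arms. They held 275 measured miRNAs, of which 7 passed, 6 rising and 1 falling. Some miRNAs stand in several lists, such as miR-21-5p in the astrocyte, immune and hypoxia lists and miR-23a-3p in the oligodendrocyte and vascular lists. Lists were tested with limma camera at a correlation of 0.01, with camera at an estimated correlation and with fry. Members were also counted with p adjusted over their list alone, which corrects neither for the 23 lists nor for shared members.

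The test was tried on simulated data for the CMS and Control comparison, with 657 miRNAs, 200 of them changed, in 20 simulations. Means and spreads came from the fit to the real values. Changed miRNAs were drawn from those with a mean of at least 10. The test recovered 44.4% of 1.5-fold changes, 79.3% of 2-fold changes and 97.9% of 4-fold changes, with 4.74% wrong calls. With no change simulated it made 1.1 calls on average. The recovered shares do not cover a mean under 10, where 16 of the 27 calls in the real data lay. Simulated errors were independent between miRNAs, so no library deviated as a whole, and changes went up or down at random. In the real data Control 1 stood apart from the other Controls, and most calls were higher in CMS. The simulated rates may therefore be more favourable than those for the real data.

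Alternatives were quantile normalization, rescaling by a trimmed mean of log ratios (30% of ratios and 5% of levels trimmed at each end), no filter beyond a value above 0, a minimum mean of 10, no mean-variance trend, pseudocounts of 0.1 and 10, leaving out the 10 most abundant miRNAs, leaving out each sample, a replicate block, and keeping only the more abundant arm in the lists. Fits on annotated miRNAs alone and with a minimum mean of 2 were added after the data were seen. Gene order came from a RefSeq gene table of the GRCr8 assembly, used only for names and neighbours. Of 468 annotated miRNAs tested, 432 matched 1 gene there. No coordinates are printed, and miRNA sequences, GC content and reads were not used here. Some predicted miRNAs carry the values of an annotated one within 1%, namely chr19_15564 (miR-24-3p), chr3_29471 (miR-130a-3p) and chr6_37176 (miR-1193-3p). The same reads may stand behind both, so these values are uncertain. The same holds for let-7a-1-3p and let-7c-2-3p, whose values are nearly identical.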

Results

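MicroRNAs (miRNAs), short RNAs that repress messenger RNAs, were profiled by sequencing in the medial prefrontal cortex of 6 rats. The medial prefrontal cortex is a frontal brain area involved in the control of mood and of the stress response. Of these rats, 3 were Controls that were left alone for 4 weeks apart from handling and cage cleaning. The other 3 went through chronic mild stress (CMS), a rodent model of depression in which mild stressors such as restraint, cold swimming and food or water deprivation alternate in random order, also for 4 weeks. Each library came from 1 rat. The table listed 1465 miRNAs, of which 694 were annotated rat miRNAs and 771 were predicted by the authors from the reads. Values were normalized and rounded to whole numbers, and they summed to between 709674 and 736078 per library. The sequencing depth behind them is unknown, so no counting interval is given. Between 448 and 477 annotated miRNAs had a value in each library. The 10 most abundant miRNAs held 47.4% to 49.9% of each library's total.

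The design asks which miRNAs differ between stressed and undisturbed rats. Of 657 miRNAs tested, 22 rose in CMS and 5 fell (limma-trend, Benjamini-Hochberg adjusted p under 0.05, n = 3 per group). Among the calls with a mean of at least 100, the largest log2 change was that of miR-127-3p, a miRNA of the imprinted Dlk1-Dio3 region. It fell 5.04-fold, from 11878.7 ± 2364.9 in Control to 2356.7 ± 146.2 in CMS (mean ± SD, n = 3 each). Both miR-23a-3p, which is encoded with miR-27a and miR-24-2, and miR-21-5p, which rises in many kinds of tissue injury and inflammation, were higher in every CMS library than in any Control library. The level of miR-23a-3p was 1.97-fold higher in CMS and that of miR-21-5p was 1.63-fold higher.

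For miR-127-3p the log2 change was -2.32 ± 0.16 (SE), with a limma adjusted p of 0.00285. The other arm of its hairpin, miR-127-5p, chosen after its values were seen, was at 1361.7 ± 281.2 in Control and 1102.7 ± 171.2 in CMS and did not pass (limma adjusted p = 0.385). The annotated miRNA miR-6321 had a value of 19 in each Control library and was blank in each CMS library (limma adjusted p = 4.9e-05). With CMS listed at 0, no fold is given for it. The annotated miRNA miR-215 also fell and had low values of 4 ± 1 in Control and 1 in each CMS library (limma adjusted p = 0.0242).

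Among annotated miRNAs, 11 rose. The level of miR-23a-3p went from 591.3 ± 55 to 1164 ± 93.5, a log2 change of 0.98 ± 0.12 (limma adjusted p = 0.0157). The level of miR-21-5p went from 2118.3 ± 29.1 to 3448 ± 211.6, a log2 change of 0.70 ± 0.09 (limma adjusted p = 0.0159). The remaining annotated miRNAs that rose were at low levels. Both arms of the miR-490 hairpin, which lies in an intron of the muscarinic receptor gene Chrm2, rose. Its 5p arm went from 1.67 ± 0.577 to 8.67 ± 2.08 (limma adjusted p = 0.017). Its 3p arm, chosen after its values were seen, went from 9.33 ± 4.04 to 33.3 ± 7.02 (limma adjusted p = 0.0386). The minor arm miR-27b-5p went from 6.67 ± 0.577 to 15 ± 2 (limma adjusted p = 0.0245). The minor arm miR-128-1-5p went from 4 ± 1 to 12.7 ± 2.52 (limma adjusted p = 0.0281). Both miR-9b-3p and miR-3064-3p were blank in all Control libraries and had a value of 1 in each CMS library (limma adjusted p = 0.017 for each), which is the smallest value the table can hold.

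**Figure D1:**
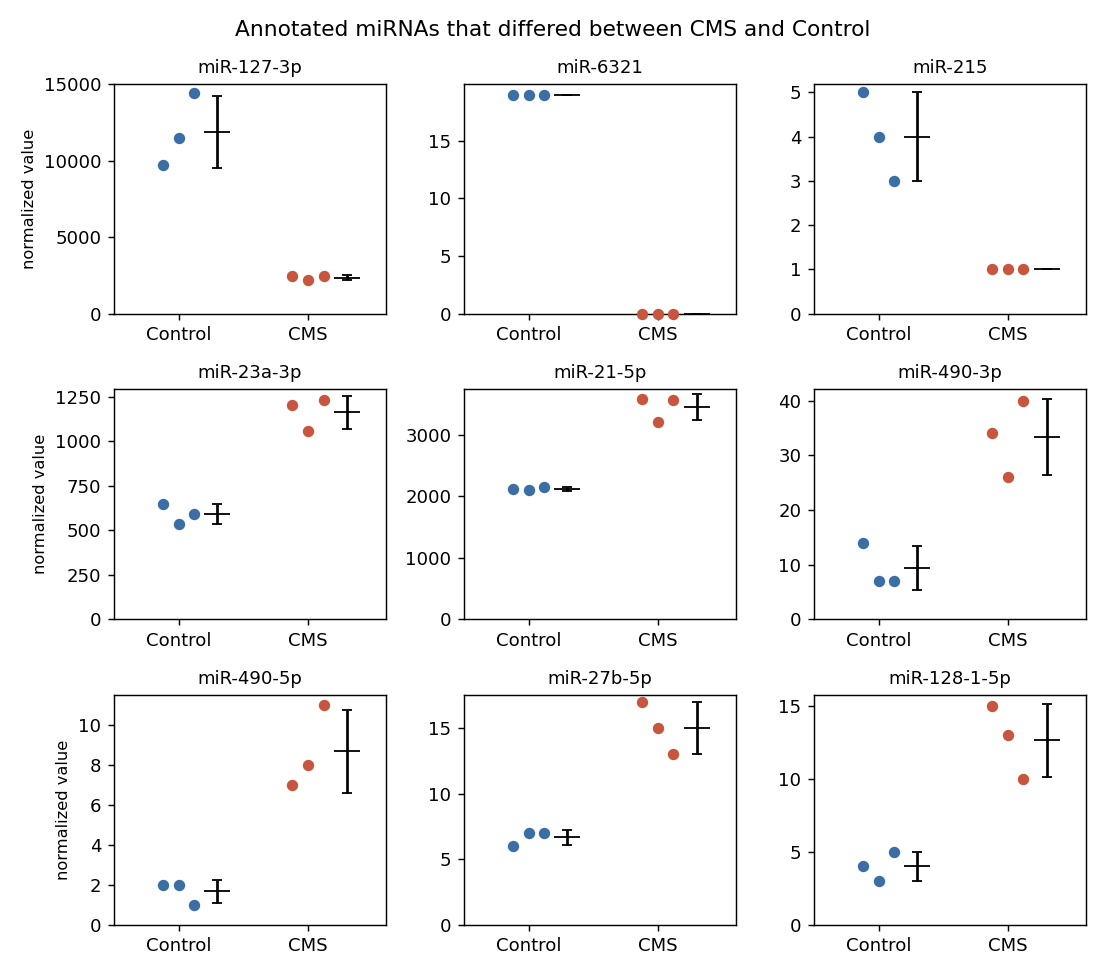
Normalized value (vertical axes, linear, each starting at 0) of 9 annotated miRNAs that passed the adjusted threshold, by group. Each point is 1 library, and the bar beside the points gives the mean ± SD of the 3 libraries. The miR-127-3p values of the CMS libraries lie near 2356.7, below all Control values, and miR-6321 is at 19 in each Control library and blank, drawn at 0, in each CMS library. Panels were chosen after the values were seen.

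Of the 13 predicted miRNAs that passed, 11 rose and 2 fell. At the highest levels, predicted miRNA chr1_21556 was 3.17-fold higher in CMS and predicted miRNA chr14_8167 was 3.84-fold higher (limma adjusted p = 0.017 for each). Predicted miRNA chr11_3476 went from a mean of 2.33 to 23.7, and predicted miRNA chr13_7341 from 3.67 to 18.7 (limma adjusted p = 0.0104 for each). Predicted miRNA chr19_15815 went from 7 to 27.7 (limma adjusted p = 0.017), and chr11_3684 from 1 to 5.33 (limma adjusted p = 0.0365). Predicted miRNAs chr7_40784 and chr1_16809 were listed at 0 in Control and had CMS means of 2.33 and 5.33. The 2 that fell, chr2_23725 and chr3_29449, had Control means of 3.67 and 1.67 and were listed at 0 in CMS. Among all 27 that passed, 16 had a mean under 10 over the 6 libraries and 5 had a mean of at least 100.

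**Figure D2:**
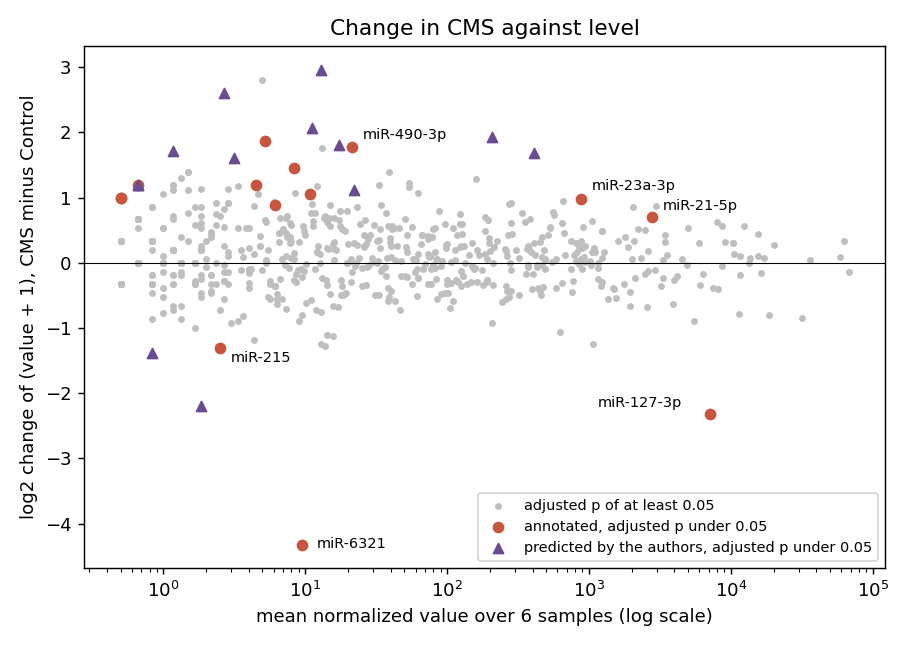
Log2 change of (value + 1) in CMS against Control (vertical axis) by the mean normalized value over the 6 libraries (horizontal axis, log scale) for the 657 miRNAs tested. Of the 27 past the adjusted threshold, 16 lie below a mean of 10, and miR-127-3p, miR-21-5p and miR-23a-3p are the annotated ones above 100. Where a group is listed at 0, as for miR-6321, the height of the point depends on the added 1.

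At an unadjusted p under 0.05 there were 153 miRNAs, 116 higher and 37 lower, against 32.8 that chance would give. Values of the groups did not overlap for 170 miRNAs (25.9%), against 10% by chance. Libraries are few, and the count of 27 depended on each of them: it was 55 without Control 1, 13 without Control 2, 9 without Control 3, 2 without CMS 1, 8 without CMS 2 and 5 without CMS 3. It was also 11 with annotated miRNAs alone, and rescaling the libraries by a trimmed mean gave 15 higher and 8 lower in place of 22 and 5. The fall of miR-127-3p passed in each of these fits. The rise of miR-23a-3p was lost without Control 3, CMS 1 or CMS 3 (limma adjusted p up to 0.0836), and the rise of miR-21-5p without Control 2, Control 3, CMS 1 or CMS 3 (limma adjusted p up to 0.0836). The call of miR-6321 passed without any 1 CMS library and was not tested without a Control library. Each low-level miRNA named above lost its call without at least 1 library, apart from miR-9b-3p, miR-3064-3p and predicted miRNA chr7_40784, which were not tested without a CMS library. None of the 6 calls with a mean under 1 was kept in the median of 100 draws that added random offsets within the range of rounding. Such offsets are large against values this small, so the loss does not show what made these calls.

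None of the 10 most abundant miRNAs passed. The most abundant, miR-26a-5p, was at 71153 ± 9199.1 in Control and 64598 ± 8462.6 in CMS (limma adjusted p = 0.565). The neuronal miRNA miR-9a-5p was at 55343.7 ± 3889.5 and 70120.3 ± 9983.1 (limma adjusted p = 0.199). The log2 differences of miR-99a-5p (0.09), let-7g-5p (0.04), let-7i-5p (0.07), let-7f-5p (0.11), miR-30a-5p (-0.16) and miR-29a-3p (0.27) did not pass either. The level of miR-7a-5p was 23702.7 ± 5252.5 in Control and 13529.7 ± 2362.6 in CMS (limma adjusted p = 0.0895), and it passed with trimmed-mean rescaling (limma adjusted p = 0.0283) and with a minimum mean of 10 (limma adjusted p = 0.0475). Neuronal miR-128-3p differed widely among the Controls, at 18158 in Control 1 and 54214 and 54272 in Controls 2 and 3. Its CMS mean was 21707 ± 6597, and the difference did not pass (limma adjusted p = 0.319).

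Lists of cell type markers were compared to see which kinds of cells the changes touched. Adjustment over a list alone depends on the length of the list and does not correct for the number of lists. Passing it alone is therefore weaker evidence than passing over all miRNAs. Of 31 measured neuronal miRNAs, 2 rose (miR-9b-3p and miR-128-1-5p, both at low levels) and none fell. Adjusted over the list alone, 3 passed, the third being miR-129-5p at 2075 ± 225.1 and 2931 ± 75.1 (limma adjusted p = 0.0541 over all miRNAs). Brain-specific miR-124-3p, chosen after its values were seen, was at 2285.3 ± 219.8 in Control and 2399.7 ± 143.6 in CMS (limma adjusted p = 0.714). Of 13 oligodendrocyte miRNAs, 2 rose (miR-23a-3p and miR-27b-5p), and 4 passed when adjusted over the list alone, with miR-27b-3p and miR-23b-3p added. None of 3 arms of miR-219a and miR-338, chosen after their values were seen, passed: miR-219a-2-3p was at 1408 ± 138.9 and 1817.3 ± 502.7 (limma adjusted p = 0.344), miR-219a-5p at 6.33 ± 2.08 and 2.33 ± 1.53 (limma adjusted p = 0.152) and miR-338-3p at 179.7 ± 1.53 and 172.3 ± 49.8 (limma adjusted p = 0.836).

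Of 20 astrocyte miRNAs, 1 rose (miR-21-5p), and 1 passed when adjusted over the list alone. The astrocyte member miR-145-5p was at 405.3 ± 74.2 and 709.7 ± 212.1 (limma adjusted p = 0.145). Of 13 microglial and immune miRNAs, 1 rose, again miR-21-5p. Adjusted over the list alone 2 passed, the other being the lymphocyte miRNA miR-150-5p at 423.7 ± 10.4 and 707 ± 110.4 (limma adjusted p = 0.0505 over all miRNAs). Of 16 vascular miRNAs, 1 rose (miR-23a-3p), and 1 passed when adjusted over the list alone. None of 15 blood miRNAs passed over all miRNAs, and 1 passed when adjusted over the list alone (miR-25-3p, at 511.3 ± 62.5 and 776.7 ± 34.5). The erythrocyte miRNA miR-451-5p was at 100.3 ± 74.5 and 218 ± 76.7 (limma adjusted p = 0.22). None of 15 choroid plexus, ependymal and epithelial miRNAs and none of 6 muscle miRNAs passed, over all miRNAs or adjusted over the list alone. In the choroid plexus list miR-200b-3p was at 5.67 ± 3.21 and 20.7 ± 8.5 (limma adjusted p = 0.13), and in the muscle list miR-1-3p was at 21.7 ± 10.5 and 9.67 ± 5.51 (limma adjusted p = 0.258). Members of the choroid plexus list were higher in Control 1 than in the other Controls, with a median log2 difference of 0.47.

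Of 52 miRNAs named in earlier stress or depression studies, miR-127-3p fell and none rose, and 1 passed when adjusted over the list alone. That list was drawn from general knowledge of the field before the values were seen. Members such as miR-195-5p, at 432 ± 64.4 and 624.3 ± 6.43 (limma adjusted p = 0.0819), and miR-30a-3p, at 740.3 ± 54.6 and 1088.7 ± 112.3 (limma adjusted p = 0.0541), did not pass. None of 34 miRNAs tied to neuronal activity or synapses passed, over all miRNAs or adjusted over the list alone. Among these, miR-381-3p was at 4773 ± 335.4 and 3093.7 ± 545.2 (limma adjusted p = 0.0819) and miR-181a-5p at 2136 ± 707.5 and 3809 ± 606.3 (limma adjusted p = 0.114). Without Control 1, miR-181a-5p and miR-384-5p of this list passed (limma adjusted p = 0.0309 and 0.0373), as did miR-195-5p of the stress list (limma adjusted p = 0.0291). With a minimum mean of 10, miR-181a-1-3p of the activity list passed (limma adjusted p = 0.0475). None of 13 miRNAs described as acting on the glucocorticoid receptor transcript passed, and 1 did when adjusted over the list alone (miR-150-5p). Of 7 miRNAs of hypoxia and cell stress, miR-21-5p rose, and 1 passed when adjusted over the list alone.

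Of 79 measured miRNAs on the list for the Dlk1-Dio3 imprinted region, whose miRNAs are transcribed from the maternal chromosome, miR-127-3p fell and none rose. Only miR-127-3p passed when adjusted over the list alone. Among the 64 other list members with a mean of at least 10, the median log2 difference was -0.01 and 33 were negative. They ranged from -1.25 for miR-543-3p, chosen after its values were seen, to 0.8 for miR-323-5p, and neither of these passed (limma adjusted p = 0.225 and 0.0517). Genes of miR-1193-3p (log2 difference 0.16) and miR-6331 (-0.34), which are not on the list, lie in the same run of genes, and neither passed (limma adjusted p = 0.698 and 0.36). Both were chosen after their values were seen.

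**Figure D3:**
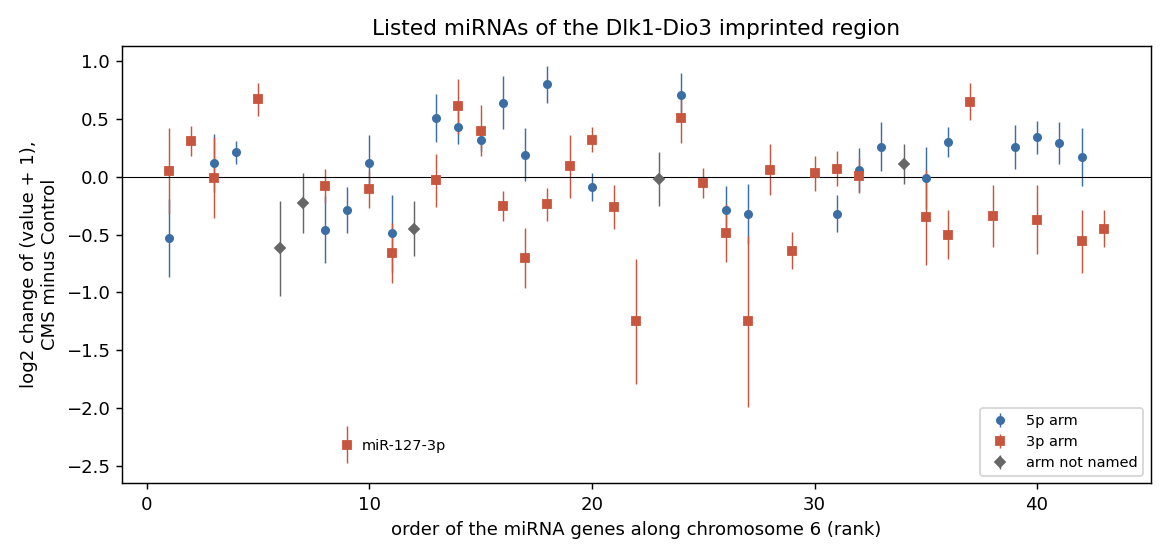
Log2 change of (value + 1) in CMS against Control (vertical axis, points with SE bars) for the 65 list members of the Dlk1-Dio3 region with a mean of at least 10, in the order of their genes on the GRCr8 assembly (horizontal axis, rank without distances). The 3p arm of miR-127 lies at -2.32, its 5p arm at -0.29, and the next lowest member at -1.25.

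Seed families and genomic clusters were compared in the same way. Both arms of a hairpin count as members, so not every member carries the seed of its family. In the let-7 family 1 of 21 members rose, the minor arm let-7a-2-3p, which was listed at 0 in Control and had a CMS mean of 1.33 (limma adjusted p = 0.0386). It was also the 1 member that passed when adjusted over the list alone. No member passed over all miRNAs in the miR-17-92 cluster and its paralogues (17 members), the miR-30 family (11), the miR-15 and miR-16 family (10), the miR-181 family (8), the miR-29 family (6), the miR-34 and miR-449 family (6), the miR-200 family (4), the miR-212 and miR-132 cluster (4) or the miR-183 cluster (3). Adjusted over the list alone, 2 members passed in the miR-17-92 list (miR-25-3p and miR-93-5p), 2 in the miR-30 family (miR-30a-3p and miR-30e-3p), 2 in the miR-200 family (miR-200b-3p and miR-200c-3p) and 0 in the remaining families. Log2 differences of the miR-30 5p arms lay between -0.89 (miR-30e-5p) and 0 (miR-30d-5p). In the longer choroid plexus list miR-200b-3p and miR-200c-3p did not pass, nor over all miRNAs (limma adjusted p = 0.13 and 0.1).

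As whole lists, none of the 23 passed limma camera at an inter-gene correlation of 0.01, either after adjustment (smallest adjusted p = 0.366) or at an unadjusted p under 0.05 (smallest p = 0.0566, for the muscle list). With an estimated correlation the count was also 0 both ways. The limma test fry, which asks whether a list moves one way on balance, gave 0 after adjustment and 2 at an unadjusted p under 0.05. These were the oligodendrocyte list and the miR-17-92 list, both upward (limma adjusted p = 0.239 for each). The mixed test of fry, which takes changes in either direction, passed for 15 lists. This test does not compare a list with the other miRNAs, and 153 of all 657 were at an unadjusted p under 0.05. Passing it therefore does not set a list apart from the rest. Without Control 1 camera called 1 list, the imprinted region, downward (adjusted p = 0.0487), and that call was lost with an estimated correlation (adjusted p = 0.943). Camera compares a list with all other miRNAs, so its direction differed in sign from the list's median or mean for the neuronal, stress, glucocorticoid receptor, imprinted region, let-7, miR-212 and miR-132, and miR-34 and miR-449 lists.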

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

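Restricting to annotated miRNAs, a minimum mean of 2 and the alternatives of the list member and arm counts were added after the data were seen. The sequencing depth is not known, so depth could not be weighed. The count of 27 changed miRNAs stayed within 1.5 times under quantile normalization (23, of which 22 are among the 27), trimmed-mean rescaling (23, 20 shared), no filter (22, 22 shared), a minimum mean of 10 (25, 11 shared, with 399 tested), no trend (32, 27 shared), pseudocounts of 0.1 (40, 27 shared) and 10 (18, 18 shared), the 10 most abundant left out (27, 27 shared) and a minimum mean of 2 (21, 18 shared). It was 11 with annotated miRNAs only, where 468 were tested. Leaving out each sample gave 2 to 55. The count at unadjusted p stayed within 1.5 times in all alternatives. Trimmed-mean rescaling and quantile normalization each moved the log2 changes of single miRNAs by a median of -0.12. The share of calls that were higher in CMS was 81.5%, 65.2% with rescaling and 78.3% with quantile normalization. Changes of the size of that shift are relative to the scaling chosen.

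The labels number the replicates 1 to 3 in both groups, but the numbers did not pair the samples: deviations of same-numbered samples correlated at -0.14, -0.06 and 0. With the replicate block the count of changed miRNAs was 1 (miR-6321), against 142 at unadjusted p, list members passing were 0, and hairpins with a changed arm ratio were 35. No sample correlated best with the sample of its own number in the other group.

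Of 23 lists, 0 passed camera in the alternatives except without Control 1, so leaving out samples gave 0 to 1. The 7 list members became 11 with a pseudocount of 0.1 and 1 to 21 over the samples left out. The 19 hairpins with a changed arm ratio became 2 to 47 over the samples left out, with the same direction of all 19 in each.

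The 20 named miRNAs past the threshold kept their direction wherever they were tested. The call of miR-127-3p held in 16 of 17 alternatives (adjusted p 6.29e-05 to 0.0703, lost with the block), miR-6321 in 13 of 13, miR-23a-3p in 13 of 17 (0.00571 to 0.0836) and miR-21-5p in 12 of 17 (0.0135 to 0.0866). The call of miR-128-1-5p held in 8 of 16. Over all named miRNAs and alternatives, 1386 results were unchanged, 92 lost the threshold, 21 gained it and 22 changed sign. Those that changed sign had not passed, and the cause was not tested. With quantile normalization miR-212-3p was at -0.02. With trimmed-mean rescaling miR-99a-5p was at -0.03, let-7g-5p at -0.09, let-7i-5p at -0.05, let-7f-5p at -0.01, miR-212-3p at 0 and miR-132-3p at -0.05. Over the samples left out, let-7g-5p lay between -0.09 and 0.21, miR-132-3p between -0.06 and 0.24, miR-183-5p between -0.35 and 0.98, miR-429 between -0.17 and 0.63, miR-212-5p between -0.08 and 0.13, miR-212-3p between -0.12 and 0.43, miR-30a-5p between -0.32 and 0.11, and miR-34a-5p between -0.08 and 0.32.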

Other observations

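The tests in this part were chosen after the result they bear on was seen, except the test of neighbouring miRNA genes and the split count for lists, and the genes used in them are not independent replicates. The miRNAs named here outside the naming rule were also chosen after their values were seen. Arm ratios, neighbouring genes, the sum of predicted miRNAs, Control 1, low-level calls and miR-127-3p were the 6 patterns looked at. Their single p-values (6 tests) were adjusted together by Benjamini-Hochberg. Of these, 2 tests compare sums of 3 against 3 libraries and cannot go below 0.1. Over the other 4 tests the adjusted values lie between 0.031 and 0.0372. Over all 6 tests the Fisher test of Control 1 was at 0.0465. The Fisher test of arms and both permutation tests of neighbours were at 0.0558. The values over all 6 are the ones to go by, and the tests of neighbours with and without the region share genes.

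Most miRNA hairpins give a 5p and a 3p arm, and the ratio of the arms cancels any scaling between libraries. Of 91 hairpins with both arms at a mean of at least 10, 19 had a ratio that differed between CMS and Control (limma, adjusted p under 0.05), and 41 did at an unadjusted p under 0.05. The 3p arm was lower relative to the 5p arm in 14 of these 19 and higher in 5. Over all 91 hairpins it was lower in 47, with a median log2 change of the ratio of -0.03. The list of the imprinted region held 8 of the 19. Apart from miR-127, where the log2 ratio changed by -2.02 ± 0.19 (SE), the clearest was miR-148b at -1.18 ± 0.19 (limma adjusted p = 0.0047). Its major arm miR-148b-3p was at 3137 ± 435.2 in Control and 1955 ± 214.5 in CMS, and its minor arm miR-148b-5p at 28 ± 6.08 and 39.7 ± 2.89 (SD, n = 3). The ratio of miR-30e moved the other way, by 1.28 ± 0.3 (limma adjusted p = 0.0208), with miR-30e-5p at 7054.7 ± 1044 and 3967.3 ± 1349.6 and miR-30e-3p at 1536.3 ± 43.3 and 2026.7 ± 158.9. Ratios of miR-29b (-0.82) and miR-29c (-0.87) also fell, while that of miR-29a, the most abundant of this family, was at 0.04 ± 0.31 and did not pass (limma adjusted p = 0.901). Within the list of the imprinted region 16 of 22 hairpins had a relatively lower 3p arm, against 31 of 69 elsewhere (two-sided exact Fisher p = 0.0285, 0.0558 after adjustment). Without Control 1, Control 2 or Control 3 the count of 19 was 47, 8 or 2. Without CMS 1, CMS 2 or CMS 3 it was 13, 6 or 11. Other splits of the 6 samples into 3 and 3 gave at most 0 hairpins, so 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05.

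Neighbouring miRNA genes, often cut from 1 transcript, may have changed together. Among 229 genes matched to GRCr8, 98 lay in 26 clusters whose genes start at most 10 kb apart. The intraclass correlation of their log2 changes was 0.0807 (one-sided permutation p = 0.0286 from 10000 shuffles, 0.0558 after adjustment), and without the clusters of the imprinted region it was 0.29 (permutation p = 0.0372, 0.0558 after adjustment). In 1 cluster miR-25-3p and miR-93-5p were at 0.61 and 0.62 and miR-106b-5p at 0.01. In another miR-23b-3p was at 0.52 and miR-27b-3p at 0.44. Next to miR-23a-3p at 0.98, miR-27a-3p was at 0.03. Among clustered genes outside the imprinted region, the largest changes were those of miR-200a-3p (1.17) and miR-200b-3p (1.76), which form 1 cluster. Both were at low levels and did not pass (limma adjusted p = 0.223 and 0.13). How far the correlation rests on this pair was not tested.

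Predicted miRNAs summed to 4360 ± 128.3 in Control and 5776.3 ± 275.7 in CMS, a 1.32-fold higher level, and the lowest CMS sum lay 1020 above the highest Control sum. The two-sided exact permutation p was 0.1, the smallest that 3 against 3 allows, so it could not have passed and says nothing against the rise. Without the 3 predicted miRNAs that share their values with an annotated one the ratio was 1.31 (exact permutation p = 0.1). Predicted miRNAs chr1_21556 (means of 197 in Control and 624.3 in CMS) and chr14_8167 (85.7 and 328.7), both called above, carry much of this rise. In the full sum chr19_15564, which shares its values with miR-24-3p, adds to it (1039 and 1442). A higher sum therefore does not mean that predicted miRNAs rose broadly. The sum is therefore not separate from those calls. All predicted miRNAs together make up 0.576% to 0.824% of a library.

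The fall of miR-127-3p stood out at its level. It was not shared by the region: the median log2 change of the 64 other list members with a mean of at least 10 was -0.01 and the lowest was -1.25, which argues against a lower output of the whole region. Scaling between libraries did not account for it, since trimmed-mean rescaling gave -2.44 (limma adjusted p = 6.29e-05, over all alternatives 6.29e-05 to 0.0703). A handling difference between the groups that acts on single sequences stays open: of 83 annotated miRNAs with a mean of at least 1000, miR-127-3p was the 1 that passed and changed more than 2-fold, while miR-543-3p lay at -1.25 without passing (limma adjusted p = 0.225) and the arm ratios of miR-148b and miR-30e also changed. Such a difference cannot be told apart from an effect of stress, since reads and preparation dates were not used here.

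Of the 27 calls, 16 had a mean under 10, where rounding matters. Values were redrawn 100 times within the range that rounding hides. Of 6 calls with a mean under 1, miR-9b-3p, miR-3064-3p and let-7a-2-3p among them, a median of 0 were kept. Random offsets are large against values this small, so these calls could be lost whether or not the levels differed. The draws cannot tell whether rounding made these calls, and they remain uncertain. Of 10 calls with a mean of 1 to 10, a median of 9 were kept, though the division at 1 was made after 9 of 16 in all had been seen to hold. The redrawn values gave a median of 40 calls in all (21 to 45), against 27 in the main fit. Since the redrawn fits usually made more calls, keeping 9 of 10 does not settle whether rounding played a part. With trimmed-mean rescaling 9 of the 16 remained past the threshold. With quantile normalization the calls lost among the 16 were miR-128-1-5p, miR-488-5p and miR-6329. A part played by scaling stays open.

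Control 1 stood apart from the other Controls, at -1.51 on a first principal component (55.4% of the variance) where Controls 2 and 3 lay at -7.16 and -7.32 and the CMS libraries between 4.16 and 6.98, and across miRNAs it correlated better with CMS 2 (0.9868) and CMS 3 (0.9867) than with Control 2 (0.9831) or Control 3 (0.9858). Without it 55 miRNAs passed in place of 27, of which 18 were shared. Its choroid plexus, ependymal and epithelial list lay above the other Controls in 13 of 15 members (median 0.47, above 99.8% of 10000 random lists matched on level), with miR-204-5p, also in the astrocyte list, at 1413 against 687 and 652, so more of such tissue is a candidate explanation for that part. It does not account for the low miRNAs, which made up 14 of the 15 largest deviations at a mean of at least 100: miR-128-3p lay at -1.58, but the 18 neuronal miRNAs at that level had a median of -0.2 (quartiles -0.5 and 0.01) and miR-124-3p lay at 0.02, where dilution by other tissue would lower them alike. For a CMS library under a Control label 3 tests were tried in turn. At the 55 calls made without it, Control 1 lay in the 25% of the range next to the other Controls at 18 (32.7%), against 0 of 15 for left-out CMS libraries (two-sided exact Fisher p = 0.00775, 0.0465 after adjustment), but also against 8 of 13 for left-out Control 2 and 6 of 9 for Control 3. Its median position there was 0.55 of the way to CMS, where Control 2 and Control 3 lay at 0.16 and 0. The 15 calls pool 3 leave-outs, and miR-127-3p and miR-6321 were called in each. The Fisher test counted such repeats as separate, so its p is a rough guide. At 213 miRNAs with unadjusted p under 0.05 without it, Control 1 lay beyond the CMS libraries on the Control side at 58.7%. That was above left-out CMS 1 (35.9% of 117) and CMS 3 (44% of 109) and below CMS 2 (64.6% of 144). A left-out CMS library has fewer CMS libraries to lie beyond than Control 1, which raises its share, so these shares are not measured alike. A wrong label cannot be told apart from a Control that differs.

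Over the 10 splits of the 6 samples, the real split gave 27 changed miRNAs and the highest other 0, 153 at unadjusted p and the highest other 65, and 7 list members and the highest other 0. In each case 1 of 10 splits gave as many. For lists the real count was 0 and the highest other 5, so all 10 splits gave as many. The design is too small for a share under 0.05. The 3 splits that exchange Control 1 with a CMS library gave 42, 46 and 65 at unadjusted p, more than the remaining 6.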
